A study of Danio rerio with 6 samples.

How the data were processed

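RNA-seq was measured in sorted zebrafish intestinal epithelial cells, with 3 libraries at 3 dpf and 3 at 5 dpf. According to the labels, pools of embryos had their heads removed and were dissociated with trypsin and collagenase. Cells positive for tdTomato and negative for a viability dye were then sorted. RNA was made into libraries with the KAPA HyperPrep kit and sequenced as read pairs on a NovaSeq X Plus, and all samples carried batch 1. The design text names non-transgenic controls, which were not analysed here.

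The deposited files hold raw counts of fragments per gene, made by the authors with featureCounts and not normalized. Per the file headers, featureCounts 1.6.3 counted read pairs as fragments over exons grouped by gene, with strand setting 2, on the Ensembl release 115 annotation of GRCz11. Reads that map to several places or lie over several genes were not counted, so levels of near-identical paralogs are uncertain. The submitters' processing notes name Trimmomatic 0.38, STAR 2.7.11 and Subread 1.6.3. Each file lists 32520 genes, of which 29201 were paired with a symbol. Some symbols are written in human style and 6136 genes share a symbol with another, so Ensembl IDs are given for shared symbols. Library totals ran from 102653637 to 125456069 counts.

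Genes were tested with edgeR 4.0.16 (quasi-likelihood F-test, two-sided) in R 4.3.3, with TMM normalization and the age as the only term. The filter was filterByExpr, with a minimum count of 10 and a minimum total of 15. Benjamini-Hochberg adjustment covered all genes tested, with a threshold of 0.05. TMM factors were 1.021, 1.001 and 1.112 for the 3 dpf libraries and 0.612, 1.136 and 1.266 for the 5 dpf libraries. Log2 CPM used a prior count of 2, and levels are given as CPM scaled by these factors. With library size alone, ratios of 5 dpf replicate 1 to the other 5 dpf libraries would all lie lower. Libraries are pools, and p-values measure only the spread between pooled samples. No label says that equal replicate numbers mark a shared day. For libraries of the same number the deviations from the mean of their age correlated at 0.092, -0.217 and 0.193 across genes, so no block was used.

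Gene lists, 30 on functions of the tissue and 17 of markers for other cell types, the tests and the alternatives were chosen before the data were examined, except where stated. Of 1905 entries written, 751 matched a symbol as written, 649 in another letter case, 357 after a copy suffix was dropped and 9 through a synonym, while 139 matched none. Lists with at least 5 tested members were tested with camera (limma 3.58.1, two-sided) with a preset correlation of 0.01 between genes, adjusted over all lists. The correlation was also estimated per list. With the estimated correlation 0 lists passed, so each camera call depends on the preset value, and splits that mixed the ages gave calls too. The fry test asks whether the genes of a list move on balance in a direction, without comparing them with other genes.

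Named genes followed a rule. It took cldn15la and, among called genes with a symbol, CPM that did not overlap and a mean of at least 10 CPM at the higher age, the 12 with the largest log2 fold change in each direction. From each functional list it took up to 2 called members with the largest changes in the more frequent direction and 1 in the other, at 5 CPM or more. From a list with 0 called at 5 CPM or more it took the 2 of highest mean CPM. From each marker list it took the most abundant member on no functional list, and it added the 10 most abundant genes of each age. Genes chosen after their values were seen are said to be so. A few genes that the rule took are not described. Values without each library in turn are in the order of 3 dpf and then 5 dpf replicates.

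Where an age had 0 counts, the fold change was bounded against 3 counts over the 3 libraries. With 1 to 3 counts the ratio is given with a 95% interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Intervals on differences of medians are bootstraps over genes, not libraries. In simulated data 50 genes changed at each of 4 sizes. There edgeR recovered 0% at 1.5-fold, 0% at 2-fold, 64% at 4-fold and 100% at 8-fold, with 5 of 87 calls wrong. DESeq2 recovered 0%, 12%, 94% and 100%, with 52 of 155 calls wrong. A seeded list was recovered by camera (p = 2.06e-36, or 0.000238 with an estimated correlation), an unchanged one not (p = 0.904). Estimated correlations of real lists reached 0.991, so this does not vouch for the preset value.

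Alternatives were RLE, upper quartile and library size scaling, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, a block for the replicate number, each library left out in turn, thinning to the smallest total, and leaving out the 20 most abundant genes or the marker genes. Leaving out both 5 dpf replicate 1 and 3 dpf replicate 3, and leaving out mitochondrial genes, were added after the data were seen. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.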

Results

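Intestinal epithelial cells of the zebrafish were profiled by RNA-seq at 3 and 5 days post fertilization (dpf), about when larvae begin to feed. The cells had been sorted by flow cytometry on tdTomato, a red fluorescent protein knocked in at cldn15la, a claudin gene of the gut epithelium. Each age had 3 libraries, and the comparison asked how gene expression in these cells differed between the ages. Total counts were 102653637, 113035974 and 113267448 in 3 dpf replicates 1, 2 and 3, and 124702821, 125456069 and 112315914 in the 5 dpf replicates. Counts from the mitochondrial chromosome made up 7.91, 11.4 and 8.99% of the 3 dpf libraries and 29.2, 10.3 and 9.59% of the 5 dpf libraries, in replicate order.

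The libraries separated by age on the first principal component of log2 CPM, which held 65.5% of the variance. On the second, which held 22.4%, 5 dpf replicate 1 separated from the other 5 dpf libraries. Across genes, which are not independent replicates, the 3 dpf libraries correlated at 0.977 to 0.984 and 5 dpf replicates 2 and 3 at 0.983. The correlation of 5 dpf replicate 1 with those libraries was 0.923 and 0.928, and correlations between the ages were 0.863 to 0.915. The sample titled 3 dpf replicate 3 carried a treatment tag of 4 dpf and was grouped by its title. Its position on the first component was -92.5, against -121.3 and -108.5 for the other 3 dpf libraries and 95.4 to 123.1 at 5 dpf.

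**Figure D1:**
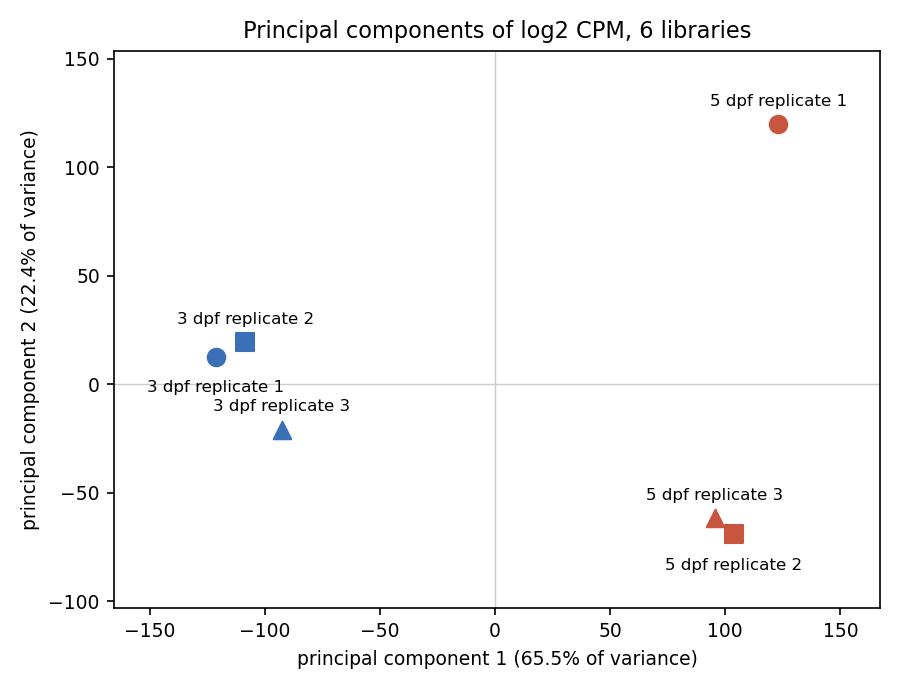
Principal components of log2 CPM over the genes tested, with each axis giving the position of a library on a component and the share of variance it holds. The 3 dpf libraries lie at -121.3 to -92.5 on the first component and the 5 dpf libraries at 95.4 to 123.1, while 5 dpf replicate 1 lies at 119.8 on the second against -69.1 and -61.8 for the other 5 dpf libraries.

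The sorting marker cldn15la (ENSDARG00000016081, chromosome 2, 5508542 to 5517438 of GRCz11) stood at 632 ± 93.4 CPM at 3 dpf and 568 ± 293 at 5 dpf (mean ± SD, n = 3 per age). Its log2 fold change was -0.16 (SE 0.37), which did not pass the test (edgeR adjusted p = 0.779). Single libraries measured 682, 690.4 and 525 CPM at 3 dpf and 900.4, 457 and 347 CPM at 5 dpf, in replicate order. Since the cells were sorted on this locus, its level describes the sort. Without 5 dpf replicate 1 the log2 fold change was -0.65 (edgeR adjusted p = 0.0281), and without 5 dpf replicate 3 it was 0.10.

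Between 3 and 5 dpf many genes of digestion, absorption and secretion rose in these sorted pools, and most genes of proliferation and ribosome production fell. A shift in the shares of epithelial cell types was not tested and stays open. Of the brush border hydrolases 14 of 22 rose, as did 28 of 47 genes of lipid absorption, 25 of 55 enteroendocrine genes and 20 of 33 goblet cell genes. In the other direction, 52 of 54 S phase genes, 58 of 63 genes of G2 and mitosis and 69 of 93 ribosome biogenesis genes fell. insl5a, a gut hormone gene chosen after its values were seen, rose from 3.5 ± 2.04 to 591 ± 107 CPM (log2 fold change 7.4, SE 0.53). SOX4 (ENSDARG00000098834, chromosome 16, 68069 to 71108), a transcription factor of immature cells, fell from 1197 ± 126 to 225 ± 67.4 CPM (log2 fold change -2.41, SE 0.30). CPM are means ± SD over 3 libraries per age, log2 fold changes are 5 dpf over 3 dpf, and rose or fell is used of genes that passed edgeR's quasi-likelihood test.

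In that test 7194 of 22386 genes passed a Benjamini-Hochberg adjusted p of 0.05, of which 4045 (56.2%) were higher at 5 dpf and 3149 lower. At least a 2-fold change was seen in 5614 of them, 3672 higher and 1942 lower. The CPM of the ages did not overlap for 11259 genes (50.3%), against 10% by chance for 3 libraries against 3. With library size as the only scaling 65.3% of 3849 calls were higher, and with upper quartile scaling 65.3% of 7121 were. Upper quartile scaling moved the median log2 fold change of all genes tested from 0.09 to 0.22. Leaving out 5 dpf replicate 1 gave 10628 calls, among them 7131 of the 7194, and leaving out 3 dpf replicate 3 gave 5293. With both left out there were 11902 calls. Without 3 dpf replicate 1 there were 3003, and without 3 dpf replicate 2 there were 3590.

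**Figure D2:**
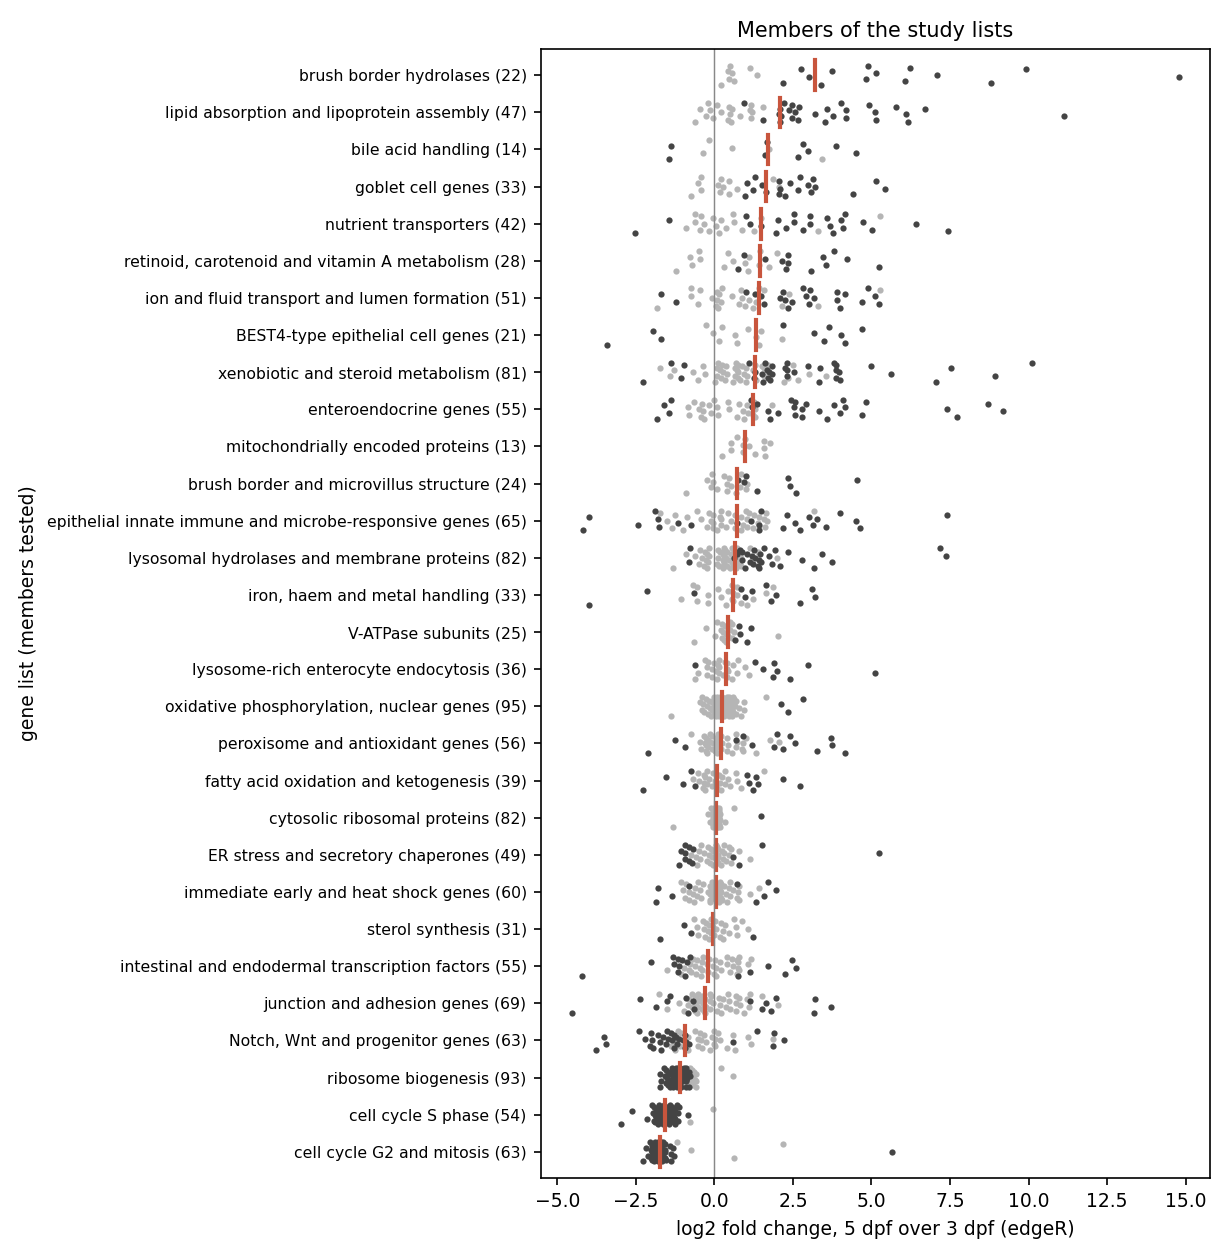
Log2 fold change of each tested member of the study lists (horizontal axis, 5 dpf over 3 dpf), with members that passed the test in dark grey, the others in light grey, and the list median as a red bar. List medians run from 3.19 for brush border hydrolases to -1.73 for G2 and mitosis, and those of oxidative phosphorylation and cytosolic ribosomal proteins, 0.25 and 0.05, become -0.43 and -0.42 without 5 dpf replicate 1 (the former -0.02 with library size as the only scaling).

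Most of the enzymes that finish digestion at the enterocyte surface rose. Of the brush border hydrolases 14 of 22 rose and 0 fell, or 14 and 0 adjusted over the list alone. The hydrolase list had a median log2 fold change of 3.19 (camera adjusted p = 9.47e-10, or 0.31 with an estimated correlation). mep1a.1, a meprin subunit gene, rose from 0.0949 ± 0.114 to 93.2 ± 99.5 CPM (log2 fold change 9.91, SE 1.33, or 11.36 without 3 dpf replicate 2 and 8.54 without 5 dpf replicate 1). MEP1B (ENSDARG00000037533, chromosome 20, 6493648 to 6516539), another meprin gene, had 0 counts at 3 dpf and 8317 at 5 dpf, at least 2640-fold higher against a floor of 3 counts over the 3 dpf libraries. In 5 dpf replicates 1, 2 and 3 it stood at 70.8, 7.67 and 12.8 CPM, and the bound was 1170-fold without 5 dpf replicate 1 and 1670-fold without 3 dpf replicate 3. Of the genes that build the microvillus 8 of 24 rose and 0 fell, or 10 and 1 adjusted over the list alone. Of the microvillus genes 4, 5 and 5 rose without 3 dpf replicates 1, 2 and 3 in turn, while 1 fell without 3 dpf replicate 3 and 5 dpf replicate 1 in turn. For the microvillus list the median log2 fold change was 0.71 (camera adjusted p = 0.0264, or 0.589 with an estimated correlation). The microvillus test was lost without 3 dpf replicate 3 and 5 dpf replicate 1 in turn (camera adjusted p = 0.0538 and 0.0511). The microvillus adjusted p was 0.0616 with fry and 0.0900 without both 5 dpf replicate 1 and 3 dpf replicate 3. tmigd1, a membrane protein gene, rose from 0.797 ± 0.253 to 18.7 ± 14.2 CPM (log2 fold change 4.55, SE 0.60, or 3.73 without 5 dpf replicate 1). ESPN, which bundles actin, rose from 3.59 ± 0.915 to 21.6 ± 14.7 CPM (log2 fold change 2.59, SE 0.49, or 1.88 without 5 dpf replicate 1). Within the age, 5 dpf replicate 1 lay above the mean of the other 5 dpf libraries by a median log2 ratio of 1.88 for the hydrolases and 0.84 for the microvillus genes.

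Transporters and lipid-handling genes of the enterocyte rose more often than they fell. Of the nutrient transporters 21 of 42 rose and 2 fell, or 25 and 2 adjusted over the list alone. Among transporter genes 12 rose without 3 dpf replicate 1, while 1, 1, 2, 3, 1 and 1 fell without each library in turn. Across transporter genes the median log2 fold change was 1.49 (camera adjusted p = 4.9e-05, or 0.589 with an estimated correlation). The transporter adjusted p was 0.0672 with fry. SLC15A1 (ENSDARG00000100315, chromosome 9, 1137430 to 1162804), the peptide transporter PepT1, rose from 1.56 ± 1.26 to 134 ± 143 CPM (log2 fold change 6.42, SE 1.03, or 7.28 without 3 dpf replicate 2 and 5.04 without 5 dpf replicate 1). SLC6A18, of the neutral amino acid transporter family, rose from 0.152 ± 0.045 to 26.2 ± 18.3 CPM (log2 fold change 7.42, SE 0.65, or 6.71 without 5 dpf replicate 1). SLC13A3, a dicarboxylate transporter gene, fell from 59.7 ± 12.4 to 10.4 ± 7.3 CPM (log2 fold change -2.52, SE 0.56, or -3.16 without 5 dpf replicate 3). In lipid absorption and lipoprotein assembly 28 of 47 rose and 0 fell, or 30 and 0 adjusted over the list alone. On the lipid list 14 and 18 rose without 3 dpf replicates 1 and 3 in turn, while 1 fell without 5 dpf replicate 1. The lipid list had a median log2 fold change of 2.1 (camera adjusted p = 2.46e-08, or 0.589 with an estimated correlation). The lipid median was 1.32 without 5 dpf replicate 1. The lipid adjusted p was 0.0756 with fry. apoea (ENSDARG00000102004, chromosome 19, 10855158 to 10859694), an apolipoprotein gene, rose from 0.268 ± 0.0985 to 609 ± 449 CPM (log2 fold change 11.14, SE 0.79, or 10.34 without 5 dpf replicate 1). apoa4b.3, an apolipoprotein gene with near-identical copies and so of uncertain level, rose from 1.12 ± 0.482 to 118 ± 128 CPM (log2 fold change 6.72, SE 0.92, or 5.31 without 5 dpf replicate 1). The median log2 ratio of 5 dpf replicate 1 to the other 5 dpf libraries was 1.21 for the nutrient transporters and 1.64 for the lipid list.

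Among genes for bile acids, foreign compounds and vitamin A, more rose than fell. Among bile acid genes 7 of 14 rose and 2 fell, or 9 and 2 adjusted over the list alone. Of the bile acid genes 4 rose without 3 dpf replicate 1, while 0, 0, 1, 3, 1 and 0 fell without each library in turn. For the bile acid list the median log2 fold change was 1.7 (camera adjusted p = 0.0572). The bile acid test passed without 3 dpf replicate 2 and 5 dpf replicates 2 and 3 in turn (camera adjusted p = 0.0151, 0.00642 and 0.0221). The bile acid adjusted p was 0.0152 with library size as the only scaling, 0.0298 with no filter on low counts and 0.0296 with the replicate block. FABP6, the ileal bile acid binding protein, rose from 43.1 ± 22 to 973 ± 1005 CPM (log2 fold change 4.5, SE 0.83, or 3.2 without 5 dpf replicate 1). slco2b1, an organic anion carrier, rose from 3.16 ± 1.88 to 24.9 ± 9.14 CPM (log2 fold change 2.98, SE 0.47). slco1d1, another carrier, fell from 425 ± 114 to 164 ± 62 CPM (log2 fold change -1.38, SE 0.35). The slco1d1 call ended without 3 dpf replicate 1 or 2 or 5 dpf replicate 3 (edgeR adjusted p = 0.059 to 0.0822). In xenobiotic and steroid metabolism 32 of 81 rose and 4 fell, or 34 and 5 adjusted over the list alone. Among xenobiotic genes 12, 18 and 14 rose without 3 dpf replicates 1, 2 and 3 in turn, while 0, 0, 1, 7, 1 and 2 fell without each library in turn. Across xenobiotic genes the median log2 fold change was 1.29 (camera adjusted p = 0.000115, or 0.663 with an estimated correlation). The xenobiotic median was 0.42 without 5 dpf replicate 1. The xenobiotic adjusted p was 0.165 with fry. cyp2ad2, a cytochrome P450 gene, rose from 0.0379 ± 0.0438 to 42.6 ± 46.6 CPM (log2 fold change 10.09, SE 1.22, or 8.66 without 5 dpf replicate 1). Without 3 dpf replicate 2 cyp2ad2 had 3 counts at 3 dpf, a ratio of 2520 (862 to 12200). cyp2n13, of the same family, rose from 0.456 ± 0.486 to 223 ± 236 CPM (log2 fold change 8.93, SE 1.24, or 10.29 without 3 dpf replicate 2 and 7.58 without 5 dpf replicate 1). ugt1b7, a glucuronosyltransferase gene, fell from 7.94 ± 2.08 to 1.63 ± 0.991 CPM (log2 fold change -2.29, SE 0.56). The ugt1b7 call ended without 3 dpf replicate 1 or 2 (edgeR adjusted p = 0.0637 to 0.0646). In retinoid and carotenoid metabolism 13 of 28 rose and 0 fell, or 15 and 0 adjusted over the list alone. On the retinoid list 6, 7 and 7 rose without 3 dpf replicates 1, 2 and 3 in turn, while 2 fell without 5 dpf replicate 1. The retinoid list had a median log2 fold change of 1.44 (camera adjusted p = 0.00173, or 0.426 with an estimated correlation). bco1l, a carotenoid oxygenase gene, rose from 3.76 ± 3.26 to 140.5 ± 129.9 CPM (log2 fold change 5.22, SE 0.91, or 6.2 without 3 dpf replicate 2 and 4.14 without 5 dpf replicate 1). RBP4, the retinol carrier, rose from 5.53 ± 2.49 to 104 ± 52.3 CPM (log2 fold change 4.23, SE 0.54). In 5 dpf replicate 1 the median log2 ratio to the other 5 dpf libraries was 1.28 for bile acid genes, 1.82 for the xenobiotic list and 1.36 for the retinoid list.

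Lysosome-rich enterocytes take up protein from the gut lumen by endocytosis. CUBN (ENSDARG00000087013, chromosome 24, 32035759 to 32150276), the cubilin receptor, rose from 2.2 ± 0.898 to 76.8 ± 72.8 CPM (log2 fold change 5.12, SE 0.77, or 4.00 without 5 dpf replicate 1). lrp2b, a megalin gene, rose from 8.32 ± 2.08 to 65.8 ± 31.1 CPM (log2 fold change 2.98, SE 0.38). ctsbb, a cathepsin B gene, rose from 0.512 ± 0.225 to 85.6 ± 99 CPM (log2 fold change 7.38, SE 1.02, or 5.8 without 5 dpf replicate 1). ctsl.1, a cathepsin L gene, rose from 2.36 ± 0.826 to 341 ± 399.6 CPM (log2 fold change 7.18, SE 1.0, or 5.55 without 5 dpf replicate 1). In 5 dpf replicates 1, 2 and 3, CUBN stood at 160.4, 27.5 and 42.4 CPM and ctsl.1 at 802, 118 and 103 CPM. Of the lysosomal hydrolases and membrane proteins 30 of 82 rose and 2 fell, or 34 and 2 adjusted over the list alone. Of the lysosomal genes 7 and 10 rose without 3 dpf replicates 1 and 2 in turn, while 0, 0, 1, 6, 0 and 0 fell without each library in turn. For the lysosomal list the median log2 fold change was 0.64 (camera adjusted p = 0.000666, or 0.589 with an estimated correlation). On the endocytosis list 8 of 36 rose and 1 fell, or 8 and 1 adjusted over the list alone. Among endocytosis genes 3, 4 and 4 rose without 3 dpf replicates 1, 2 and 3 in turn, while 0, 0, 0, 3, 0 and 0 fell without each library in turn. Across endocytosis genes the median log2 fold change was 0.37 (camera adjusted p = 0.111). The endocytosis adjusted p was 0.0448 with fry and 0.0268 among genes of at least 1 CPM in 3 libraries. AP2M1 (ENSDARG00000033899), a clathrin adaptor gene, fell from 112 ± 8.88 to 73.6 ± 2.38 CPM (log2 fold change -0.61, SE 0.17). The AP2M1 call ended without 3 dpf replicate 1, 2 or 3 or 5 dpf replicate 2 or 3 (edgeR adjusted p = 0.0555 to 0.145). NPC1, which exports cholesterol from lysosomes, fell from 151 ± 42 to 86.1 ± 10.4 CPM (log2 fold change -0.81, SE 0.26). The NPC1 call ended without 3 dpf replicate 1 or 2 or 5 dpf replicate 2 or 3 (edgeR adjusted p = 0.103 to 0.168). Of the V-ATPase subunits, which acidify lysosomes, 5 of 25 rose and 0 fell, or 4 and 0 adjusted over the list alone. On the V-ATPase list 0, 0 and 2 rose without 3 dpf replicates 1 and 2 and 5 dpf replicate 2 in turn. The V-ATPase list had a median log2 fold change of 0.43 (camera adjusted p = 0.0977). The V-ATPase test passed without 3 dpf replicate 3 (camera adjusted p = 0.0351). The V-ATPase adjusted p was 0.0451 with fry and 0.0249 among genes of at least 1 CPM in 3 libraries. ATP6V1C1 (ENSDARG00000035880) rose from 5.77 ± 1.6 to 12.8 ± 1.74 CPM (log2 fold change 1.16, SE 0.26). The ATP6V1C1 call ended without 3 dpf replicate 1 or 2 (edgeR adjusted p = 0.0682 to 0.0768). atp6v0e1 rose from 12.5 ± 0.324 to 25.9 ± 9.28 CPM (log2 fold change 1.05, SE 0.27). The atp6v0e1 call ended without 3 dpf replicate 1, 2 or 3 (edgeR adjusted p = 0.0703 to 0.0871). For 5 dpf replicate 1 against the other 5 dpf libraries the median log2 ratio was 0.52 for the lysosomal list, 0.36 for endocytosis and 0.18 for V-ATPase.

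Most genes of cell division fell. For S phase 0 of 54 rose and 52 fell, or 0 and 53 adjusted over the list alone. Across S phase genes the median log2 fold change was -1.57 (camera adjusted p = 2.27e-28, or 0.31 with an estimated correlation). For G2 and mitosis 1 of 63 rose and 58 fell, or 1 and 59 adjusted over the list alone. For the mitosis list the median log2 fold change was -1.73 (camera adjusted p = 1.58e-30, or 0.322 with an estimated correlation). RRM2 (ENSDARG00000020711), the small subunit of ribonucleotide reductase, fell from 90.3 ± 36.4 to 11.4 ± 4.57 CPM (log2 fold change -2.98, SE 0.44). RRM2 (ENSDARG00000078069), another copy, fell from 76.3 ± 32.8 to 12.3 ± 1.91 CPM (log2 fold change -2.63, SE 0.37). CCNA2, cyclin A2, fell from 70.8 ± 3.6 to 14.7 ± 5.33 CPM (log2 fold change -2.27, SE 0.30). CDC20, an activator of the anaphase-promoting complex, fell from 72 ± 5.78 to 15.9 ± 7.58 CPM (log2 fold change -2.17, SE 0.36). mki67, a marker of cycling cells chosen after its values were seen, fell from 649 ± 35.8 to 175 ± 75.1 CPM (log2 fold change -1.89, SE 0.36). Of the ribosome biogenesis genes 0 of 93 rose and 69 fell, or 0 and 81 adjusted over the list alone. Among ribosome biogenesis genes 28, 28, 67, 91, 43 and 39 fell without each library in turn. Across ribosome biogenesis genes the median log2 fold change was -1.1 (camera adjusted p = 2.37e-19, or 0.55 with an estimated correlation). BOP1, of large subunit maturation, fell from 124 ± 25.5 to 37 ± 4.99 CPM (log2 fold change -1.75, SE 0.23). tcof1, the treacle gene of ribosomal RNA transcription, fell from 49.1 ± 7.53 to 14.8 ± 2.59 CPM (log2 fold change -1.73, SE 0.22). The log2 ratio of 5 dpf replicate 1 to the other 5 dpf libraries had a median of -0.53 for S phase, -0.84 for G2 and mitosis and 0.57 for ribosome biogenesis.

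Progenitor genes and those of Notch and Wnt signalling fell more often than they rose. On that list 5 of 63 rose and 28 fell, or 5 and 35 adjusted over the list alone. On the progenitor list 3 rose without 3 dpf replicate 1, while 12 and 16 fell without 3 dpf replicates 1 and 2 in turn. The progenitor list had a median log2 fold change of -0.92 (camera adjusted p = 1.15e-06, or 0.322 with an estimated correlation). LIN28A (ENSDARG00000016999, chromosome 19, 15440841 to 15473157), an RNA-binding protein of early embryonic cells, fell from 44.9 ± 15.4 to 3.92 ± 2.79 CPM (log2 fold change -3.52, SE 0.55, or -4.27 without 5 dpf replicate 3). PROM1 (ENSDARG00000039966), a prominin of apical membranes, rose from 2.7 ± 0.714 to 12.5 ± 4.3 CPM (log2 fold change 2.21, SE 0.35). Of the intestinal and endodermal transcription factors 6 of 55 rose and 11 fell, or 6 and 11 adjusted over the list alone. Of the transcription factor genes 1 and 2 rose without 3 dpf replicates 1 and 2 in turn, while 3, 5 and 18 fell without 3 dpf replicates 1 and 2 and 5 dpf replicate 1 in turn. For the transcription factor list the median log2 fold change was -0.22 (camera adjusted p = 0.126). The transcription factor test passed without 3 dpf replicate 3 (camera adjusted p = 0.0452). The transcription factor adjusted p was 0.0351 without both 5 dpf replicate 1 and 3 dpf replicate 3. MYCN, a MYC family gene, fell from 61.4 ± 13.1 to 15 ± 1.99 CPM (log2 fold change -2.03, SE 0.22). ELF3, an epithelial factor, fell from 1215 ± 25.8 to 488 ± 196 CPM (log2 fold change -1.32, SE 0.33). The ELF3 call ended without 3 dpf replicate 1, 2 or 3 (edgeR adjusted p = 0.0579 to 0.0715). MAF (ENSDARG00000015890), a leucine zipper factor, rose from 1.18 ± 0.251 to 7.12 ± 5.36 CPM (log2 fold change 2.59, SE 0.56, or 1.81 without 5 dpf replicate 1). The MAF call ended without 3 dpf replicate 1 or 2 (edgeR adjusted p = 0.0538 to 0.0626). Over the same ages the summed CPM of mesenchyme markers went from 1006 ± 166 to 3250 ± 1309 and that of epidermis markers from 4201 ± 372 to 8359 ± 3268.

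Hormone genes of the gut rose more often than they fell. Of the enteroendocrine genes 25 of 55 rose and 4 fell, or 29 and 4 adjusted over the list alone. The enteroendocrine list had a median log2 fold change of 1.22 (camera adjusted p = 2.89e-09, or 0.458 with an estimated correlation). vipb (ENSDARG00000079443, chromosome 11, 43401201 to 43414172), a VIP peptide gene, rose from 0.217 ± 0.0824 to 128 ± 39.3 CPM (log2 fold change 9.2, SE 0.46). gip, the incretin GIP, rose from 0.0962 ± 0.0767 to 40.2 ± 31.1 CPM (log2 fold change 8.7, SE 1.24). In the 5 dpf libraries gip measured 4.91, 63.2 and 52.6 CPM. Further genes were chosen after their values were seen. PYY rose from 215 ± 74.9 to 2571 ± 758 CPM (log2 fold change 3.58, SE 0.39). CCK rose from 24.1 ± 5.89 to 381 ± 87.1 CPM (log2 fold change 3.98, SE 0.30). gcga, a glucagon gene that islets also express, rose from 10.4 ± 5.12 to 272 ± 40.8 CPM (log2 fold change 4.71, SE 0.41). neurog3, a factor of hormone cell precursors chosen likewise, fell from 9.01 ± 1.43 to 3.33 ± 0.862 CPM (log2 fold change -1.43, SE 0.28). pax4, of similar precursors, fell from 89.2 ± 30.5 to 25.2 ± 14.8 CPM (log2 fold change -1.82, SE 0.46). The pax4 call ended without 3 dpf replicate 1 or 3 or 5 dpf replicate 2 (edgeR adjusted p = 0.0616 to 0.0721). Summed CPM of endocrine pancreas markers, 7 of 11 tested also on another list, went from 325 ± 92.6 to 679.8 ± 111. The enteroendocrine list stood at a median log2 ratio of -0.67 in 5 dpf replicate 1 against the other 5 dpf libraries.

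More goblet cell, BEST4-type and ion transport genes rose than fell. Of the goblet cell genes 20 of 33 rose and 0 fell, or 21 and 0 adjusted over the list alone. Of the goblet genes 1 fell without 5 dpf replicate 1. For the goblet list the median log2 fold change was 1.64 (camera adjusted p = 1.82e-07, or 0.31 with an estimated correlation). FER1L6, a ferlin, rose from 3.03 ± 1.91 to 131 ± 25.1 CPM (log2 fold change 5.43, SE 0.61). clca1, a protein secreted with mucus, rose from 0.317 ± 0.201 to 11.4 ± 13.5 CPM (log2 fold change 5.15, SE 1.0, or 5.79 without 3 dpf replicate 3 and 3.5 without 5 dpf replicate 1). Of the genes for BEST4-type cells, an epithelial type rich in ion channels, 7 of 21 rose and 3 fell, or 9 and 3 adjusted over the list alone. Among BEST4 genes 11 rose without 5 dpf replicate 1. Across BEST4 genes the median log2 fold change was 1.34 (camera adjusted p = 0.0572). The BEST4 test passed without 3 dpf replicates 1 and 3 and 5 dpf replicate 1 in turn (camera adjusted p = 0.0386, 0.0383 and 0.0168). The BEST4 adjusted p was 0.0381 with library size as the only scaling, 0.034 with no filter on low counts, 0.0403 among genes of at least 1 CPM in 3 libraries, 0.000826 with the replicate block and 0.0011 without both 5 dpf replicate 1 and 3 dpf replicate 3. BEST4, a bestrophin channel, rose from 12.4 ± 6.08 to 221 ± 105 CPM (log2 fold change 4.15, SE 0.56). CFTR, the chloride channel, rose from 21.2 ± 11.1 to 548 ± 193 CPM (log2 fold change 4.69, SE 0.53). SFRP5, a secreted Wnt antagonist, fell from 82.8 ± 23.2 to 7.67 ± 3.38 CPM (log2 fold change -3.43, SE 0.41). Among genes of ion and fluid transport 22 of 51 rose and 2 fell, or 27 and 2 adjusted over the list alone. On the ion transport list 13 rose without 3 dpf replicate 1, while 0, 0, 2, 3, 1 and 1 fell without each library in turn. The ion transport list had a median log2 fold change of 1.42 (camera adjusted p = 7.21e-05, or 0.257 with an estimated correlation). The ion transport adjusted p was 0.105 without members shared with other lists. aqp10a, an aquaporin gene, rose from 0.166 ± 0.0561 to 6.29 ± 7.59 CPM (log2 fold change 5.24, SE 1.0, or 3.54 without 5 dpf replicate 1). aqp10b, its paralog, rose from 0.208 ± 0.163 to 7.2 ± 3.98 CPM (log2 fold change 5.1, SE 0.78, or 5.73 without 3 dpf replicate 2). ATP1B1 (ENSDARG00000076833), a sodium pump subunit, fell from 61.5 ± 34.5 to 18.9 ± 3.25 CPM (log2 fold change -1.71, SE 0.47). The ATP1B1 call ended without 3 dpf replicate 1 or 2 or 5 dpf replicate 2 or 3 (edgeR adjusted p = 0.0692 to 0.103). Of the ion transport genes tested 30 were on another list too. Over the same ages 12 of 27 ionocyte markers rose (16 of the 27 also on another list), and their summed CPM went from 1225 ± 52.8 to 2295 ± 266. Median log2 ratios of 5 dpf replicate 1 to the other 5 dpf libraries were 0.39, -1.22 and 0.11 for the goblet, BEST4 and ion lists.

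**Figure D3:**
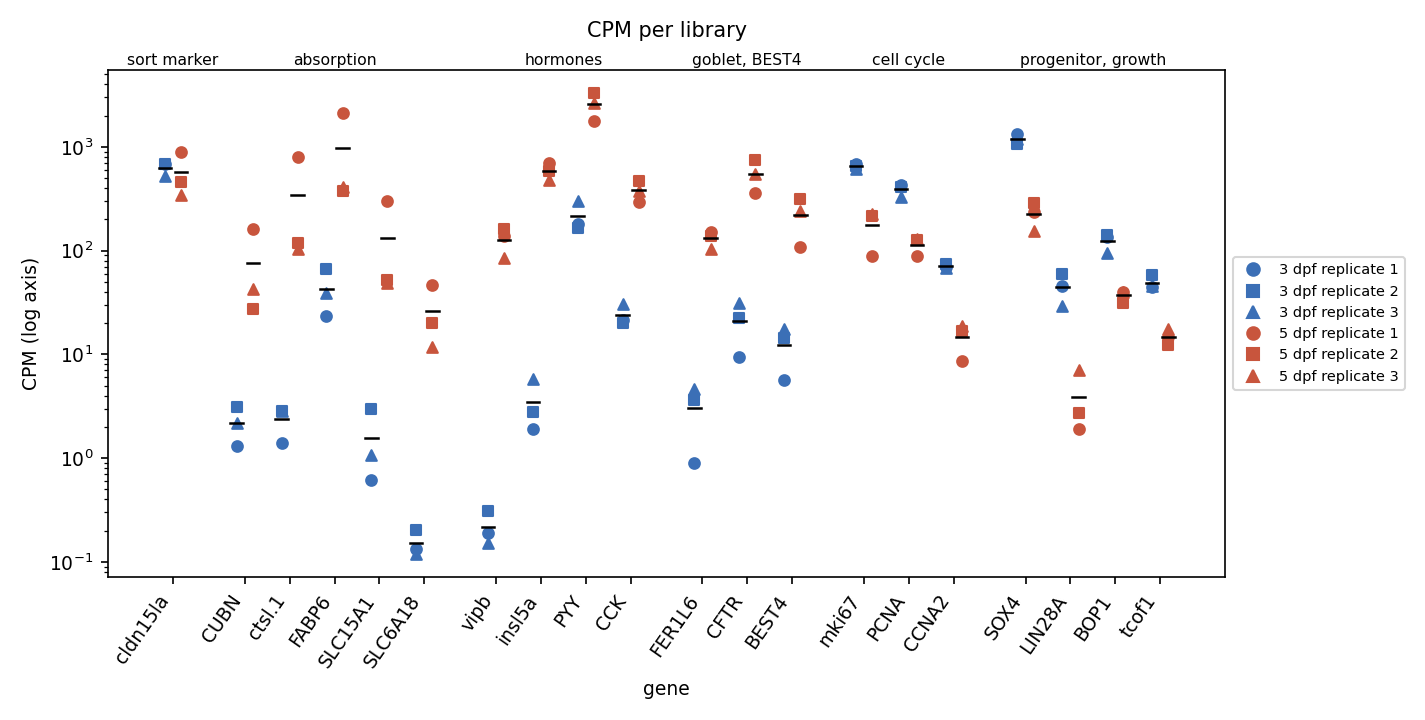
CPM of single genes on a log axis in each library, 3 dpf and 5 dpf in separate colours, with a black line at the mean of each age. CUBN, ctsl.1, FABP6, SLC15A1 and SLC6A18 stand higher in 5 dpf replicate 1 than in the other 5 dpf libraries, as CUBN with 160.4 against 27.5 and 42.4 CPM, while CFTR stands lower there, with 356 against 742 and 545 CPM.

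Barrier and defence genes went in both directions. Of the junction and adhesion genes 8 of 69 rose and 9 fell, or 7 and 7 adjusted over the list alone. Of the junction genes 4 rose without 3 dpf replicates 1, 2 and 3 in turn, while 3, 3, 9, 26, 5 and 4 fell without each library in turn. For the junction list the median log2 fold change was -0.30 (camera adjusted p = 0.111). The junction test passed without 3 dpf replicate 3 (camera adjusted p = 0.0475). The junction adjusted p was 0.0382 with library size as the only scaling and 0.0189 without both 5 dpf replicate 1 and 3 dpf replicate 3. CLDN2, a claudin, fell from 8.29 ± 2.83 to 0.356 ± 0.0527 CPM (log2 fold change -4.54, SE 0.38). LAMB1 (ENSDARG00000101209), a laminin chain, fell from 182 ± 53.6 to 35.4 ± 15.3 CPM (log2 fold change -2.36, SE 0.41). cldni, another claudin, rose from 3.21 ± 1.45 to 29.8 ± 11.3 CPM (log2 fold change 3.21, SE 0.44). Of the innate immune and microbe-responsive genes 17 of 65 rose and 8 fell, or 20 and 9 adjusted over the list alone. Among immune genes 11, 11 and 26 rose without 3 dpf replicates 1 and 2 and 5 dpf replicate 1 in turn, while 3, 3, 7, 9, 5 and 5 fell without each library in turn. Across immune genes the median log2 fold change was 0.71 (camera adjusted p = 0.0977). The immune adjusted p was 0.0495 with fry. cxcl8b.1, a chemokine gene, rose from 0.343 ± 0.234 to 5.47 ± 1.59 CPM (log2 fold change 4.00, SE 0.59, or 4.62 without 3 dpf replicate 1). c3a.1, complement component C3, fell from 202 ± 124 to 11 ± 2.96 CPM (log2 fold change -4.19, SE 0.55). In iron, haem and metal handling 9 of 33 rose and 3 fell, or 9 and 3 adjusted over the list alone. On the iron list 4 and 5 rose without 3 dpf replicates 1 and 2 in turn. The iron list had a median log2 fold change of 0.59 (camera adjusted p = 0.122). SLC40A1, the iron exporter ferroportin, rose from 6.44 ± 2.38 to 42.6 ± 9.03 CPM (log2 fold change 2.73, SE 0.33). hamp, hepcidin, which blocks that exporter, fell from 21.9 ± 16 to 1.4 ± 1.05 CPM (log2 fold change -3.98, SE 0.78, or -3.31 without 3 dpf replicate 2 and -4.76 without 5 dpf replicate 1). fthl27, a ferritin gene, rose from 349 ± 51 to 1224 ± 949 CPM (log2 fold change 1.81, SE 0.53, or 0.97 without 5 dpf replicate 1). The fthl27 call ended without 3 dpf replicate 1, 2 or 3 (edgeR adjusted p = 0.105 to 0.119).

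Stress genes, which dissociation can raise, went in both directions. Of the immediate early and heat shock genes 5 of 60 rose and 4 fell, or 3 and 4 adjusted over the list alone. Of the heat shock genes 3, 3, 3, 7, 3 and 5 rose without each library in turn, while 1, 1, 4, 10, 5 and 1 fell without each library in turn. For the heat shock list the median log2 fold change was 0.04 (camera adjusted p = 0.612). KLF9 rose from 9.79 ± 3.37 to 38.1 ± 4.03 CPM (log2 fold change 1.96, SE 0.28). BAG3, a co-chaperone gene, rose from 23.6 ± 4.87 to 77 ± 16.8 CPM (log2 fold change 1.71, SE 0.25). HSPD1, the mitochondrial chaperonin, fell from 798 ± 172 to 220.5 ± 42.1 CPM (log2 fold change -1.86, SE 0.28). Of the secretory pathway chaperones and ER stress genes 4 of 49 rose and 9 fell, or 3 and 8 adjusted over the list alone. Among chaperone genes 1, 1, 2, 4, 1 and 4 rose without each library in turn, while 1, 3 and 15 fell without 3 dpf replicates 1 and 2 and 5 dpf replicate 1 in turn. Across chaperone genes the median log2 fold change was 0.04 (camera adjusted p = 0.302). The chaperone adjusted p was 0.0461 without both 5 dpf replicate 1 and 3 dpf replicate 3. pdia2, a protein disulfide isomerase of the pancreas, rose from 2.48 ± 0.486 to 92.9 ± 34.7 CPM (log2 fold change 5.23, SE 0.35). CRELD2 fell from 20.8 ± 2.97 to 9.43 ± 0.457 CPM (log2 fold change -1.14, SE 0.19). ASNS, asparagine synthetase, fell from 98.5 ± 23.3 to 47.1 ± 14.6 CPM (log2 fold change -1.07, SE 0.29). The ASNS call ended without 3 dpf replicate 1 or 2 or 5 dpf replicate 2 (edgeR adjusted p = 0.0814 to 0.113). Of the peroxisome and antioxidant genes 12 of 56 rose and 3 fell, or 12 and 3 adjusted over the list alone. On the peroxisome list 4 and 5 rose without 3 dpf replicates 1 and 2 in turn, while 7 fell without 5 dpf replicate 1. The peroxisome list had a median log2 fold change of 0.22 (camera adjusted p = 0.231). The peroxisome test passed without 5 dpf replicate 2 (camera adjusted p = 0.0267). DAO (ENSDARG00000035603), D-amino acid oxidase, rose from 2.34 ± 0.592 to 41.5 ± 25.6 CPM (log2 fold change 4.14, SE 0.48, or 3.53 without 5 dpf replicate 1). gpx4a, a glutathione peroxidase, rose from 90.6 ± 30.7 to 869 ± 939 CPM (log2 fold change 3.26, SE 0.77, or 1.86 without 5 dpf replicate 1). The gpx4a call ended without 3 dpf replicate 1, 2 or 3 (edgeR adjusted p = 0.0517 to 0.0751). HAO1, hydroxyacid oxidase, fell from 10.7 ± 2.06 to 2.45 ± 1.22 CPM (log2 fold change -2.13, SE 0.38).

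Genes of sterol synthesis and fatty acid oxidation also went in both directions. In sterol synthesis 1 of 31 rose and 3 fell, or 1 and 2 adjusted over the list alone. Of the sterol genes 0, 2 and 2 rose without 3 dpf replicate 1 and 5 dpf replicates 1 and 2 in turn, while 1, 1, 3, 5, 1 and 2 fell without each library in turn. For the sterol list the median log2 fold change was -0.04 (camera adjusted p = 0.446). DHCR7, of the last step to cholesterol, rose from 72.7 ± 15.6 to 171 ± 39.8 CPM (log2 fold change 1.23, SE 0.26). The DHCR7 call ended without 3 dpf replicate 1 (edgeR adjusted p = 0.0533). LBR, the lamin B receptor and a sterol reductase, fell from 88.7 ± 6.1 to 26.8 ± 10.5 CPM (log2 fold change -1.73, SE 0.32). IDI1, of isoprenoid synthesis, fell from 102 ± 12.2 to 51.9 ± 13.4 CPM (log2 fold change -0.97, SE 0.24). The IDI1 call ended without 3 dpf replicate 1 or 2 or 5 dpf replicate 2 (edgeR adjusted p = 0.0649 to 0.0817). In fatty acid oxidation 7 of 39 rose and 5 fell, or 6 and 5 adjusted over the list alone. Among fatty acid genes 2 and 3 rose without 3 dpf replicates 1 and 2 in turn, while 1, 1, 3, 11, 2 and 1 fell without each library in turn. Across fatty acid genes the median log2 fold change was 0.09 (camera adjusted p = 0.932). PDK2 (ENSDARG00000059054), a kinase that restrains pyruvate oxidation, rose from 18.9 ± 5.85 to 124 ± 79.5 CPM (log2 fold change 2.71, SE 0.50, or 2.03 without 5 dpf replicate 2). ACSL1, an acyl-CoA synthetase, fell from 76.2 ± 20.9 to 15.8 ± 5.87 CPM (log2 fold change -2.27, SE 0.35).

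Calls of respiratory chain and ribosomal protein genes depended on 5 dpf replicate 1. Of the respiratory chain genes in the nucleus 3 of 95 rose and 0 fell, or 1 and 0 adjusted over the list alone. On the respiratory list 1 rose without 3 dpf replicates 1 and 2 in turn, while 47 fell without 5 dpf replicate 1. The respiratory list had a median log2 fold change of 0.25 (camera adjusted p = 0.92). The respiratory test passed without 5 dpf replicate 1 (camera adjusted p = 2.44e-05). The respiratory adjusted p was 9.55e-06 without both 5 dpf replicate 1 and 3 dpf replicate 3. Its median was -0.43 without 5 dpf replicate 1 alone and -0.02 with library size as the only scaling. cox7a1, a cytochrome oxidase subunit gene, rose from 1.77 ± 0.18 to 12.5 ± 12.3 CPM (log2 fold change 2.82, SE 0.66, or 1.61 without 5 dpf replicate 1). The cox7a1 call ended without 3 dpf replicate 1, 2 or 3 (edgeR adjusted p = 0.0582 to 0.0707). cox4i1l, of the same complex, rose from 3.85 ± 1.21 to 19.6 ± 5.35 CPM (log2 fold change 2.35, SE 0.33). Of the cytosolic ribosomal proteins 1 of 82 rose and 0 fell, or 0 and 0 adjusted over the list alone. Of the ribosomal protein genes 0 rose without 3 dpf replicates 1 and 2 in turn, while 23 fell without 5 dpf replicate 1. For the ribosomal protein list the median log2 fold change was 0.05 (camera adjusted p = 0.498). The ribosomal protein test passed without 5 dpf replicate 1 (camera adjusted p = 1.94e-05). The ribosomal protein adjusted p was 7.01e-06 without both 5 dpf replicate 1 and 3 dpf replicate 3. Its median was -0.42 without 5 dpf replicate 1 alone. RPS2 went from 2627 ± 305 to 2879 ± 1075 CPM, and RPL3 from 2608 ± 307 to 2586 ± 963. In 5 dpf replicate 1 the respiratory and ribosomal lists stood at median log2 ratios of 1.53 and 1.13 to the other 5 dpf libraries. For fatty acid oxidation, ribosomal proteins, the chaperone list, the heat shock list and biliary markers, median and mean were above 0 while camera placed them below other genes.

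Of the 13 mitochondrially encoded protein genes edgeR called 0, with 0 at an unadjusted p under 0.05, and DESeq2 called 1 higher. Without 5 dpf replicate 1 edgeR called 1 lower. Their median log2 fold change was 0.96 (camera adjusted p = 0.425), or -0.27 without 5 dpf replicate 1. MT-CO1 went from 14450 ± 3390 to 35220 ± 36860 CPM, MT-CO3 from 4306 ± 1290 to 13060 ± 14210 and MT-CO2 from 3526 ± 1030 to 10640 ± 11660. MT-CYB went from 3005 ± 781 to 8960 ± 9756 CPM and MT-ATP6 from 5251 ± 1733 to 8670 ± 9277. ENSDARG00000080337, which has no symbol and spans 2043 to 3725 of the mitochondrial chromosome, stood at 48800 ± 9318 CPM at 3 dpf and 116400 ± 123400 at 5 dpf. Other abundant genes did not pass the test. The elongation factor gene eef1a1l1 went from 10760 ± 1094 to 12230 ± 3718 CPM, and eef2b from 7209 ± 918 to 6775 ± 1446. The chaperone gene HSPA8 (ENSDARG00000068992) went from 7592 ± 494 to 7652 ± 2204 CPM, and HSP90AB1 from 7398 ± 563 to 6818 ± 2077. The actin gene actb1 went from 6451 ± 997 to 7449 ± 3862 CPM, and actb2 from 5429 ± 949.5 to 8351 ± 5026.

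Many of the highest fold changes belonged to digestive enzymes of the exocrine pancreas, which were almost silent at 3 dpf. The elastase gene ela2l (ENSDARG00000056765, chromosome 8, 21366771 to 21372485) had 0 counts at 3 dpf and 23289 at 5 dpf, at least 7400-fold higher against the floor. It measured 34.7, 116 and 28.75 CPM in the 5 dpf replicates, and the bound was 3530-fold without 5 dpf replicate 2 and 4690-fold without 3 dpf replicate 3. The chymotrypsinogen gene ctrb.2 had 2 counts at 3 dpf and 14848 at 5 dpf, a ratio of 7070 (95% counting interval 1960 to 58400). At 5 dpf ctrb.2 measured 14.2, 76.2 and 20.5 CPM, and its ratio was 3150 (871 to 26000) without 5 dpf replicate 2 and 4480 (1240 to 37000) without 3 dpf replicate 3. Without 3 dpf replicate 1 it had 0 counts at 3 dpf and was at least 3280-fold higher at 5 dpf. ctrb.1, of the same family, rose from 0.0424 ± 0.0734 to 95.7 ± 63.4 CPM (log2 fold change 11.01, SE 1.18, or 10.29 without 5 dpf replicate 2). Without 3 dpf replicate 3 ctrb.1 had 0 counts at 3 dpf and was at least 7380-fold higher at 5 dpf. ctrb.3, another copy, rose from 0.0148 ± 0.0143 to 51.4 ± 38.9 CPM (log2 fold change 11.68, SE 0.92, or 10.83 without 5 dpf replicate 2). Without 3 dpf replicate 1 ctrb.3 had 2 counts at 3 dpf, a ratio of 6610 (1830 to 54600). ela2, an elastase gene, rose from 0.0373 ± 0.031 to 56.2 ± 47.5 CPM (log2 fold change 10.5, SE 0.94, or 11.27 without 3 dpf replicate 2 and 9.51 without 5 dpf replicate 2). prss59.1, a trypsinogen gene, rose from 0.0608 ± 0.0404 to 73.5 ± 54.2 CPM (log2 fold change 10.21, SE 0.80, or 10.83 without 3 dpf replicate 2 and 9.39 without 5 dpf replicate 2). cuzd1.1, a zona pellucida domain gene, rose from 0.175 ± 0.203 to 253 ± 40.7 CPM (log2 fold change 10.48, SE 1.1, or 9.89 without 3 dpf replicate 1 and 11.85 without 3 dpf replicate 2). cuzd1.2, its neighbour in the family, rose from 0.0583 ± 0.0724 to 267 ± 13.2 CPM (log2 fold change 12.13, SE 0.80, or 13.81 without 3 dpf replicate 2). UCP1 (ENSDARG00000023151, chromosome 1, 53374454 to 53388914), a mitochondrial uncoupling protein, rose from 0.625 ± 0.163 to 1170 ± 658 CPM (log2 fold change 10.87, SE 0.65). Reads mapping to several places were not counted, so values of single ctrb, prss59 and cuzd1 copies are uncertain.

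ITIH5, oc90 and c4b fell steeply. ITIH5 (ENSDARG00000045517, chromosome 4, 25220674 to 25245817), an inter-alpha-trypsin inhibitor chain, fell from 41.1 ± 3.61 to 1.75 ± 0.665 CPM (log2 fold change -4.55, SE 0.33). c4b, of complement, fell from 23.3 ± 9.88 to 1.44 ± 0.71 CPM (log2 fold change -4.00, SE 0.51). cfh, complement factor H, fell from 20.3 ± 6.2 to 1.76 ± 0.821 CPM (log2 fold change -3.52, SE 0.45). f5, coagulation factor V, fell from 15.09 ± 12.3 to 1.39 ± 0.46 CPM (log2 fold change -3.44, SE 0.78, or -2.72 without 3 dpf replicate 2). SERPIND1, heparin cofactor II, fell from 12.5 ± 4.39 to 1.19 ± 0.576 CPM (log2 fold change -3.39, SE 0.45). serpinf2b, an antiplasmin and hepatocyte marker, fell from 59.07 ± 20.9 to 5.64 ± 2.73 CPM (log2 fold change -3.39, SE 0.48). Carry-over of liver RNA was not tested. SALL4, a zinc finger factor of early embryos, fell from 36.1 ± 33.5 to 2.88 ± 1.65 CPM (log2 fold change -3.64, SE 0.85, or -2.63 without 3 dpf replicate 2). The SALL4 call ended without 5 dpf replicate 3 (edgeR adjusted p = 0.0527). oc90, an otoconin gene, fell from 10.16 ± 7.34 to 0.536 ± 0.148 CPM (log2 fold change -4.24, SE 0.69, or -3.65 without 3 dpf replicate 2). In 3 dpf replicates 1, 2 and 3, c3a.1 measured 208, 323 and 74.2, f5 15.5, 27.23 and 2.57 and hamp 20.8, 38.4 and 6.38 CPM.

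Among the lists of markers for other cell types that passed the test, medians were above 0 apart from that of skeletal muscle. Of the exocrine pancreas markers 27 of 31 rose and 1 fell, or 27 and 1 adjusted over the list alone. Among exocrine genes 2 fell without 5 dpf replicate 1. Across exocrine genes the median log2 fold change was 8.91 (camera adjusted p = 6.18e-28, or 0.31 with an estimated correlation). The exocrine median was 8.05 without 5 dpf replicate 2. With the 8 members of 3 or fewer counts at 3 dpf at their bound the median was 8.59. Their summed CPM went from 25.7 ± 5.5 to 1147 ± 840.1. prss59.2, a trypsinogen gene, rose from 0.111 ± 0.12 to 119.5 ± 81.9 CPM (log2 fold change 10.03, SE 1.11, or 9.44 without 3 dpf replicate 2, 11.28 without 3 dpf replicate 3 and 9.27 without 5 dpf replicate 2). Of the mesenchyme and smooth muscle markers 34 of 49 rose and 1 fell, or 35 and 2 adjusted over the list alone. On the mesenchyme list 19, 22 and 21 rose without 3 dpf replicates 1, 2 and 3 in turn, while 0, 0, 1, 2, 1 and 0 fell without each library in turn. The mesenchyme list had a median log2 fold change of 2.89 (camera adjusted p = 4.25e-09, or 0.589 with an estimated correlation). The mesenchyme adjusted p was 0.0636 with fry. Of the epidermis and periderm markers 18 of 32 rose and 0 fell, or 18 and 0 adjusted over the list alone. Of the epidermis genes 9 and 10 rose without 3 dpf replicates 2 and 3 in turn. For the epidermis list the median log2 fold change was 1.56 (camera adjusted p = 3.85e-06, or 0.426 with an estimated correlation). Among them krt4, a keratin of surface epithelia, stood at 2473 ± 229 CPM at 3 dpf and 4029 ± 1018 at 5 dpf (edgeR adjusted p = 0.11). Of the notochord and cartilage markers 20 of 34 rose and 1 fell, or 23 and 1 adjusted over the list alone. Among notochord genes 10 rose without 3 dpf replicate 1. Across notochord genes the median log2 fold change was 2.17 (camera adjusted p = 2.34e-06, or 0.547 with an estimated correlation). SHH (ENSDARG00000068567), a signal of gut epithelium as well as notochord, fell from 233 ± 13 to 53.3 ± 14 CPM (log2 fold change -2.13, SE 0.25). Of the leukocyte markers 16 of 32 rose and 0 fell, or 19 and 1 adjusted over the list alone. On the leukocyte list 28 rose without 5 dpf replicate 1, while 1 fell without 3 dpf replicate 3 and 5 dpf replicate 1 in turn. The leukocyte list had a median log2 fold change of 2.25 (camera adjusted p = 2.16e-05, or 0.589 with an estimated correlation). The leukocyte adjusted p was 0.0616 with fry. Of the endothelial markers 13 of 24 rose and 1 fell, or 14 and 1 adjusted over the list alone. Of the endothelial genes 4, 7, 5, 16, 6 and 9 rose without each library in turn, while 0 fell without 3 dpf replicates 1 and 2 in turn. For the endothelial list the median log2 fold change was 1.75 (camera adjusted p = 8.45e-05, or 0.31 with an estimated correlation). The endothelial adjusted p was 0.0606 among genes of at least 1 CPM in 3 libraries.

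On the pigment cell, ionocyte, eye and swim bladder lists more markers rose than fell. Of the pigment cell markers 13 of 20 rose and 0 fell, or 16 and 0 adjusted over the list alone. Among pigment genes 5, 8 and 8 rose without 3 dpf replicates 1 and 2 and 5 dpf replicate 2 in turn. Across pigment genes the median log2 fold change was 1.9 (camera adjusted p = 8.51e-06, or 0.257 with an estimated correlation). XDH, xanthine dehydrogenase, rose from 1.82 ± 0.595 to 40.7 ± 14.5 CPM (log2 fold change 4.48, SE 0.40). Of the ionocyte markers 12 of 27 rose and 1 fell, or 14 and 2 adjusted over the list alone. On the ionocyte list 7 rose without 5 dpf replicate 2, while 0, 0, 1, 2, 0 and 0 fell without each library in turn. The ionocyte list had a median log2 fold change of 1.54 (camera adjusted p = 0.000839, or 0.257 with an estimated correlation). Of the eye and lens markers 13 of 31 rose and 0 fell, or 15 and 0 adjusted over the list alone. Of the eye genes 4, 6, 10, 20, 8 and 9 rose without each library in turn. For the eye list the median log2 fold change was 2.51 (camera adjusted p = 0.000115, or 0.31 with an estimated correlation). The eye adjusted p was 0.144 among genes of at least 1 CPM in 3 libraries. Of the swim bladder markers 7 of 15 rose and 1 fell, or 8 and 1 adjusted over the list alone. Among swim bladder genes 3, 4 and 4 rose without 3 dpf replicates 1 and 2 and 5 dpf replicate 2 in turn, while 0, 0, 1, 2, 0 and 0 fell without each library in turn. Across swim bladder genes the median log2 fold change was 0.85 (camera adjusted p = 0.0208, or 0.547 with an estimated correlation). The swim bladder test was lost without 5 dpf replicate 2 (camera adjusted p = 0.0655). The swim bladder adjusted p was 0.0653 with library size as the only scaling. Of the skeletal muscle markers 2 of 43 rose and 2 fell, or 1 and 2 adjusted over the list alone. On the muscle list 1, 1, 1, 5, 2 and 2 rose without each library in turn, while 1, 1, 2, 20, 4 and 3 fell without each library in turn. The muscle list had a median log2 fold change of -1.21 (camera adjusted p = 0.000305, or 0.615 with an estimated correlation). The muscle adjusted p was 0.17 with fry. Of the muscle markers 39 were not called, and the summed CPM of the list went from 5385 ± 1110 to 3155 ± 469.

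The remaining marker lists did not pass. Of the hepatocyte markers 10 of 26 rose and 4 fell, or 11 and 6 adjusted over the list alone. Across hepatocyte genes the median log2 fold change was 0.74 (camera adjusted p = 0.113). The hepatocyte test passed without 3 dpf replicate 2 and 5 dpf replicate 1 in turn (camera adjusted p = 0.0349 and 0.0452). Of the endocrine pancreas markers 4 of 11 rose and 0 fell, or 4 and 0 adjusted over the list alone. For the endocrine list the median log2 fold change was 0.71 (camera adjusted p = 0.0872). The endocrine adjusted p was 0.0178 with fry and 0.0175 without both 5 dpf replicate 1 and 3 dpf replicate 3. ins, insulin, rose from 0.849 ± 0.157 to 3.94 ± 1.67 CPM (log2 fold change 2.22, SE 0.39). Of the erythroid markers 5 of 19 rose and 1 fell, or 5 and 1 adjusted over the list alone. Among erythroid genes 0, 3, 2, 8, 5 and 3 rose without each library in turn. Across erythroid genes the median log2 fold change was 0.93 (camera adjusted p = 0.114). The erythroid test passed without 3 dpf replicate 2 and 5 dpf replicate 1 in turn (camera adjusted p = 0.0297 and 0.0361). The erythroid adjusted p was 0.0316 among genes of at least 1 CPM in 3 libraries. Of the neural markers 7 of 41 rose and 1 fell, or 7 and 1 adjusted over the list alone. On the neural list 3, 3 and 13 rose without 3 dpf replicates 1 and 2 and 5 dpf replicate 1 in turn. The neural list had a median log2 fold change of 0.56 (camera adjusted p = 0.0872). The neural test passed without 3 dpf replicate 3 and 5 dpf replicate 1 in turn (camera adjusted p = 0.0172 and 0.0359). The neural adjusted p was 0.00383 without both 5 dpf replicate 1 and 3 dpf replicate 3. Of the pronephros markers 6 of 29 rose and 3 fell, or 6 and 3 adjusted over the list alone. Of the pronephros genes 3 rose without 3 dpf replicate 1, while 1 fell without 3 dpf replicate 1. For the pronephros list the median log2 fold change was 0.24 (camera adjusted p = 0.616). Of the biliary markers 1 of 16 rose and 4 fell, or 2 and 4 adjusted over the list alone. Among biliary genes 6 and 2 rose without 5 dpf replicates 1 and 3 in turn, while 1 and 2 fell without 3 dpf replicates 1 and 2 in turn. Across biliary genes the median log2 fold change was 0.23 (camera adjusted p = 0.907). On several lists the most abundant marker on no functional list was not called. Their CPM are given at 3 and then 5 dpf. Of lists that passed, TAGLN (ENSDARG00000033466, mesenchyme) stood at 512 ± 159.9 and 456 ± 277, and ENO3 (muscle) at 694 ± 139.7 and 1089 ± 852. ESAM (endothelium) stood at 26.5 ± 4.33 and 29.6 ± 7.56, and NCF1 (leukocyte) at 31 ± 4.96 and 49.4 ± 13.5. ATP2B1 (ionocyte) stood at 238 ± 29.3 and 159.7 ± 25.8, and ELOVL1 (ENSDARG00000103735, swim bladder) at 269 ± 35 and 280.0 ± 34.1. Of the others, RET (neural) stood at 209.8 ± 56.5 and 209.9 ± 45.7, and lgals2b (biliary) at 1994 ± 216 and 4215 ± 2451. hbae3 (erythroid) stood at 107 ± 31.3 and 102 ± 25.2, and SLC20A1 (ENSDARG00000010641, pronephros) at 539 ± 164 and 564 ± 301.

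**Figure D4:**
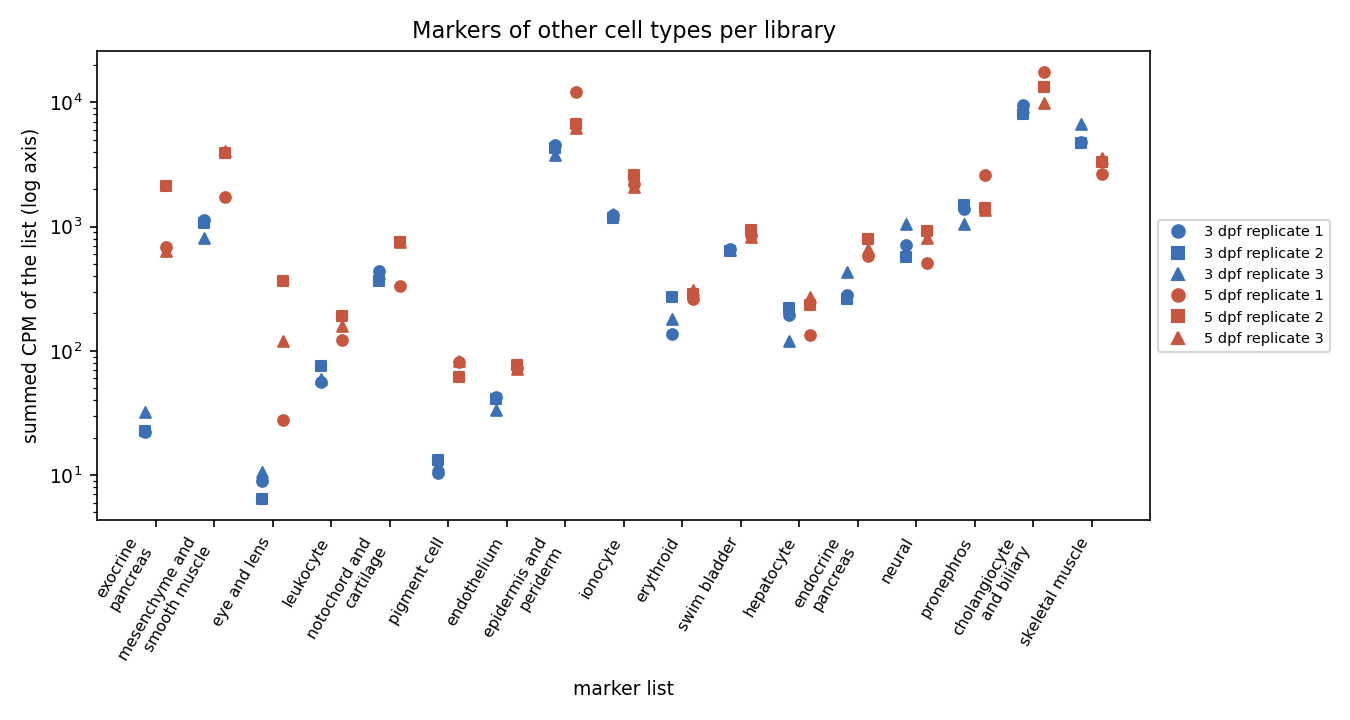
Summed CPM of each list of markers for another cell type, on a log axis, in each library. Exocrine pancreas markers average 25.7 CPM at 3 dpf and 1147 at 5 dpf, and in 5 dpf replicate 1 the mesenchyme and notochord sums lie below the other 5 dpf libraries.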

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

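The settings that left out both 5 dpf replicate 1 and 3 dpf replicate 3, or mitochondrial genes, were chosen only after the results were seen, as were all settings for the marker lists. Of 95 named genes that were called, 75 kept their direction and call in every setting run and 20 lost the call in at least 1. Of 25 that were not called, 18 took the other sign in a setting and 6 gained a call. No gene called in the comparison took the other sign in any setting. All 25 called lists lost their call with an estimated correlation, and of 22 others 14 gained a call in a setting and 7 took the other direction. Values are log2 fold changes for genes and medians for lists, where the direction compared is that of camera or fry, so a list can take the other direction with a median above 0. Causes were not tested, except that leaving out a library leaves fewer samples. With 87 edgeR calls against 7194 here, the simulated cutoff was stricter, so 0% recovery at 2-fold need not hold.

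With library size as the only scaling the values were genes called at 5 dpf against 3 dpf 3849, genes higher at 5 dpf 2512, genes lower at 5 dpf 1337, genes called with at least a 2-fold change 3713, RPS2 -0.05, RET -0.02, SLC20A1 (ENSDARG00000010641) -0.16, ELOVL1 (ENSDARG00000103735) -0.02, HSPA8 (ENSDARG00000068992) -0.14, actb1 -0.02, oxidative phosphorylation -0.02. With 5 dpf replicate 1 and 3 dpf replicate 3 both left out they were genes called at 5 dpf against 3 dpf 11902, genes higher at 5 dpf 6294, genes lower at 5 dpf 5608, cldn15la -0.79, MT-CO1 -0.15, RPS2 -0.32, hbae3 0.15, the gene ENO3 -0.38, ESAM -0.21, SLC20A1 (ENSDARG00000010641) -0.71, ENSDARG00000080337 -0.18, eef1a1l1 -0.17, HSPA8 (ENSDARG00000068992) -0.30, actb1 -0.43, actb2 -0.15, MT-ATP6 -0.82, oxidative phosphorylation -0.52, mitochondrially encoded proteins -0.44, peroxisome and antioxidant genes -0.16. With upper quartile scaling they were RPL3 0.10, hbae3 0.08, eef2b 0.03, fatty acid oxidation and ketogenesis 0.21. Among genes with at least 1 CPM in at least 3 libraries they were RPL3 0.11, hbae3 0.06, HSP90AB1 0.01, eef2b 0.04, fatty acid oxidation and ketogenesis 0.21, cytosolic ribosomal proteins 0.18, immediate early and heat shock genes 0.16, cholangiocyte and biliary 0.32.

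RLE size factors gave RET -0.02, HSPA8 (ENSDARG00000068992) -0.01. No filter on low counts gave RET -0.03, HSPA8 (ENSDARG00000068992) -0.04, oxidative phosphorylation 0.19. DESeq2 gave RET -0.03, HSPA8 (ENSDARG00000068992) -0.03. Thinning to the smallest total gave RET -0.01, HSPA8 (ENSDARG00000068992) -0.01. Leaving out the 20 most abundant genes gave RET -0.01, and leaving out mitochondrial genes RET -0.01, HSPA8 (ENSDARG00000068992) -0.01. The replicate block gave 5638 calls and SLC20A1 (ENSDARG00000010641) -0.01, HSPA8 (ENSDARG00000068992) -0.03, oxidative phosphorylation 0.05. With an estimated correlation 0 of the functional lists (gene lists) and 0 of the cell type markers lists passed. The fry test gave fatty acid oxidation and ketogenesis 0.09, immediate early and heat shock genes 0.04, cholangiocyte and biliary 0.23. Without members also on another list the value was cholangiocyte and biliary 0.84.

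Leaving out each library in turn gave ranges of genes called at 5 dpf against 3 dpf 3003 to 10628, genes higher at 5 dpf 1777 to 5748, genes lower at 5 dpf 1226 to 4880, genes called with at least a 2-fold change 2934 to 7223, cldn15la -0.65 to 0.10, MT-CO1 -0.04 to 1.69, RPS2 -0.21 to 0.31, RPL3 -0.36 to 0.15, hbae3 -0.30 to 0.13, the gene ENO3 -0.21 to 0.94, RET -0.19 to 0.20, ESAM -0.07 to 0.29, TAGLN (ENSDARG00000033466) -0.76 to 0.15, SLC20A1 (ENSDARG00000010641) -0.46 to 0.31, ELOVL1 (ENSDARG00000103735) -0.07 to 0.15, ENSDARG00000080337 -0.11 to 1.65, eef1a1l1 -0.09 to 0.33, HSPA8 (ENSDARG00000068992) -0.24 to 0.17, HSP90AB1 -0.39 to 0.02, eef2b -0.27 to 0.01, actb1 -0.29 to 0.47, MT-ATP6 -0.66 to 1.11, fatty acid oxidation and ketogenesis -0.18 to 0.25, oxidative phosphorylation -0.43 to 0.51, mitochondrially encoded proteins -0.27 to 1.36, cytosolic ribosomal proteins -0.42 to 0.28, immediate early and heat shock genes -0.32 to 0.23, cholangiocyte and biliary 0.07 to 0.37. The fewest calls came without 3 dpf replicate 1 and the most without 5 dpf replicate 1.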

Other observations

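The genes described first and the clock genes given by name, and the tests of a few genes taking the counts, of fewer cells of other types and of a lower epithelial share, were chosen only after the results were seen. Further changed genes follow. chia.1, a chitinase gene, rose from 11.8 ± 10.6 to 701 ± 724 CPM (log2 fold change 5.9, SE 1.03, or 6.92 without 3 dpf replicate 2 and 4.6 without 5 dpf replicate 1). chia.2, another chitinase gene, rose from 23.4 ± 23.8 to 4219 ± 4499 CPM (log2 fold change 7.49, SE 1.21, or 8.74 without 3 dpf replicate 2 and 6.13 without 5 dpf replicate 1). chs1, a chitin synthase gene, rose from 17.4 ± 9.32 to 337 ± 354 CPM (log2 fold change 4.28, SE 0.83, or 2.94 without 5 dpf replicate 1). DNMT1, the maintenance DNA methyltransferase, fell from 232 ± 23 to 68.3 ± 25.9 CPM (log2 fold change -1.76, SE 0.32). dnmt3ba, a methyltransferase for unmethylated DNA, fell from 159 ± 19.9 to 34.6 ± 15.7 CPM (log2 fold change -2.2, SE 0.37). LAMA5, a laminin chain, fell from 281 ± 69.6 to 77.8 ± 10.1 CPM (log2 fold change -1.85, SE 0.26). NID2, nidogen, fell from 164 ± 56.4 to 29.4 ± 8.48 CPM (log2 fold change -2.48, SE 0.35). col18a1a, collagen XVIII, fell from 848 ± 140.5 to 214 ± 35.3 CPM (log2 fold change -1.99, SE 0.25).

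PAICS, of purine synthesis, fell from 193 ± 33 to 54.7 ± 9.63 CPM (log2 fold change -1.82, SE 0.23). ATIC, of the same pathway, fell from 108 ± 21.8 to 22.9 ± 9.998 CPM (log2 fold change -2.23, SE 0.35). ADA, adenosine deaminase, rose from 58.9 ± 16.4 to 664 ± 346 CPM (log2 fold change 3.49, SE 0.43). pnp4b, a purine nucleoside phosphorylase, rose from 1.58 ± 0.163 to 135 ± 53.7 CPM (log2 fold change 6.41, SE 0.36). olfm4.1, an olfactomedin gene, rose from 14.2 ± 4.67 to 1065 ± 326 CPM (log2 fold change 6.23, SE 0.44). olfm4.2, its paralog, rose from 15.7 ± 6.48 to 1338 ± 405 CPM (log2 fold change 6.41, SE 0.49). c5, complement C5, fell from 63.5 ± 14.7 to 15.16 ± 3.91 CPM (log2 fold change -2.07, SE 0.28). bfb, complement factor B, fell from 30.6 ± 6.57 to 7.22 ± 2.31 CPM (log2 fold change -2.08, SE 0.30).

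No biological group sets 5 dpf replicate 1 apart from the other 5 dpf libraries, so no biological explanation was tested. A few genes taking most of the counts would leave the ratios between nuclear genes alike, but over 12050 genes the SD of its log2 ratio to the others was 0.98 and 0.96, at least 2.41 times the 0.40 between them. Fewer cells of other types would raise absorptive and junction genes by the same factor, but the absorptive median exceeded the junction median by 1.25 (0.78 to 1.58, medians 1.56 and 0.31), and the enteroendocrine and BEST4-type lists stood at -0.67 and -1.22. Markers of skeletal muscle at -3.04, mesenchyme at -1.98, notochord at -1.26, erythroid cells at -1.15 and eye at -4.21 went with fewer other cells. Epidermis at 0.98 did not, so a part for this stays open. Gene length bias left a difference of 0.88 (0.55 to 1.21) once the median of each length decile was taken off, above the 0.5 written beforehand for length as the whole cause but under the bound of 1 written against it, and the weight given to the interval was chosen after the value was seen, so a partial share for length stays open.

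Most marker lists for other cell types had a median log2 fold change above 0, and for these age itself stays open as untested. A lower share of epithelial cells, with the mix of the other cells unchanged, would raise every other type alike. Medians instead ran from 8.91 for exocrine pancreas to -1.21 for skeletal muscle, a span of 10.12. For skeletal muscle 39 of 43 markers were not called, and the median was -0.7 without 5 dpf replicate 1. A lower share with a mix of other cells that changed between the ages was not tested and stays open. Exocrine cells or their RNA carried past the tdTomato sort and the viability dye cannot be told apart from expression in the sorted cells for the acinar genes. The log2 ratio between 5 dpf replicates 2 and 3 had an interquartile range of 0.41 (1.64 to 2.05) over 24 of these, but 2000 sets of as many other genes had 0.25 to 0.69 (middle 95%), so the test decides nothing. The most abundant members of the list at 5 dpf were prss59.2 at 119.5 CPM, prss1 at 119 CPM and CELA1 (ENSDARG00000017314) at 118 CPM, and 0 of the 31 tested members were on another list.

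Clock genes differed between the ages, as NR1D1 with 3.68 ± 1.29 CPM at 3 dpf and 262 ± 104 at 5 dpf (log2 fold change 6.15), PER1 (ENSDARG00000056885) with a log2 fold change of 4.8 and BMAL1 (ENSDARG00000035732) with -1.86. A different hour of collection could account for this. Among 21 further clock genes, not seen before the test, the median of those cycling with nr1d1 exceeded that of those cycling with bmal1 by 1.50 (0.72 to 2.22, medians 1.11 and -0.39), or by 1.38 to 1.69 with a library left out. Of these 9 of 15 rose and 2 of 6 fell; 3 rose and 1 fell without 3 dpf replicate 1, 4 rose and 1 fell without 3 dpf replicate 2, and with other libraries left out 6 to 12 rose and 1 to 3 fell. The age itself stays open as untested.

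The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The ages gave 7194 called genes and the highest other split 0, so 1 of 10 splits gave as many. For functional lists passing camera these were 14, 22 and 9 of 10, and for marker lists 11, 10 and 1 of 10. A camera pass thus does not by itself tie a list to the ages.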
